A study of Mus musculus with 97 samples.

How the data were processed

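The authors deposited a table of TPM values made before deposit from single-end reads. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.2 and cutadapt 3.5 and quantified with Salmon (version not given) against the mouse genome GRCm39. RNA was 1000 ng per library, selected for poly(A), and sequenced for 75 cycles on a NextSeq 550. Whether the protocol kept the strand is not stated, so neighbouring genes on opposite strands may share signal. The annotation at hand was for the earlier assembly GRCm38 and served only to tell gene types, for the 20387 of 20457 gene identifiers that matched.

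The starting values were the authors' deposited TPM, used as log2(TPM + 1) with no further scaling. A gene was tested if at least 4 libraries had a TPM of 1 or more, which left 17083 of 20457 genes. A fold change on log2(TPM + 1) understates the change of genes with low values. One linear model with the 18 groups was fitted in R 4.3.3 with limma 3.58.1 (trend, robust), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were each antibiotic group with the PBS group of its route, the mix with the mean of the 4 single antibiotics of its route, and an F test of equal effects over the 3 routes. Except where stated, the groups, comparisons and alternative settings were chosen before the data were examined.

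Of 38 gene lists fixed in advance, 36 had at least 5 tested genes and were tested with camera, with its preset correlation of 0.01 and again with the correlation estimated from the data. Adjustment was over the 540 tests. Members were also counted when adjusted over the list alone. Route differences were tested for the interferon and clock lists only, a choice made after the data were seen, and were adjusted over 30 tests.

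Genes were named by a rule. Up to 8 genes with the largest rise and up to 8 with the largest fall were taken among called genes whose group mean reached the median of tested genes. Predicted and unnamed gene models, pseudogenes and antigen receptor segments, 1570 genes in all, were left out. Up to 4 called members of each list were added, with up to 2 uncalled members for contrast, and up to 6 genes for the route and mix comparisons.

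In simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 63% and 92% of them in Ampicillin-PO, and false calls stayed between 4 and 11 genes. The simulated genes varied independently of each other, and only genes above a set mean level were changed. Differences that many genes of a real library share were absent, so recovery and false calls in the real data may differ. Alternatives were a pseudocount of 10, no filter, quantile normalization, array weights, blocks, a fit of the compared groups alone, and each library left out in turn. Covariates for muscle and distal scores and settings for the appended libraries were added after the data were seen.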

Results

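RNA from the whole colon of C57BL6/J mice aged 8 to 12 weeks was sequenced after short courses of 4 antibiotics that differ in chemical class and antibacterial spectrum. Ampicillin is a beta-lactam, metronidazole a nitroimidazole active against anaerobes, neomycin an aminoglycoside and vancomycin a glycopeptide. Each was given alone, the 4 were given as a mix, and phosphate buffered saline (PBS) was the control. Every treatment was given by mouth (PO, by gavage), into the peritoneum (IP) or into a vein (IV), so the design asks what each antibiotic does to colon gene expression and whether that depends on the route. A dose was 2.5 mg in 100 µl, given 2 times a day for 3 days and 1 time on day 4, and tissue was taken 4 hours after the last dose. The amount of each drug in the mix and the clock time of tissue collection are not given in the sources used here. The 97 libraries form 18 groups of 6, except Metronidazole-IP, Metronidazole-IV, PBS-IP and Vancomycin-IP with 4 and Neomycin-IV, PBS-IV and Vancomycin-IV with 5. The values are TPM, which are scaled to one total in every library and keep no record of depth, so the depth of each library is unknown. A library held between 18247 and 19884 genes above 0. Nothing in the labels says that replicates are separate mice, so p-values measure the spread between these samples, which may be partly technical.

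The libraries differed most in how much muscle RNA they held. The first principal component carried 41.6% of the variance, with goblet and surface epithelial genes (Zg16, Tff3, Fxyd4) at one end and mesenchymal and neuronal genes (Aldh1a2, Grem1, Grp) at the other. The smooth muscle score, the mean log2(TPM + 1) of the 18 smooth muscle genes, ran from 6.99 to 11.2 over the libraries. A distal score, the mean of 5 posterior Hox genes, ran from 0.801 to 6.15. Of the 15 antibiotic groups, Vancomycin-IP stood farthest from its PBS group in muscle, with a score of 10.7 ± 0.347 (SD, n = 4) against 8.44 ± 0.429 (n = 4). That difference of 2.21 had an exact permutation p = 0.0286 on both sides, the smallest this design allows, and an adjusted p = 0.643 over the 30 score tests. Transcripts encoded by the mitochondrial genome took 3.52% to 27.5% of the TPM, with a median of 8.35%. Because of this spread each comparison was also fitted with both scores as covariates, a choice made after the data were seen. Quantile normalization moved the median change of all genes by over 0.1 in 2 comparisons. The shift was -0.17 for Vancomycin-IP against PBS-IP and 0.13 for Mix-IP against the single antibiotics.

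**Figure D1:**
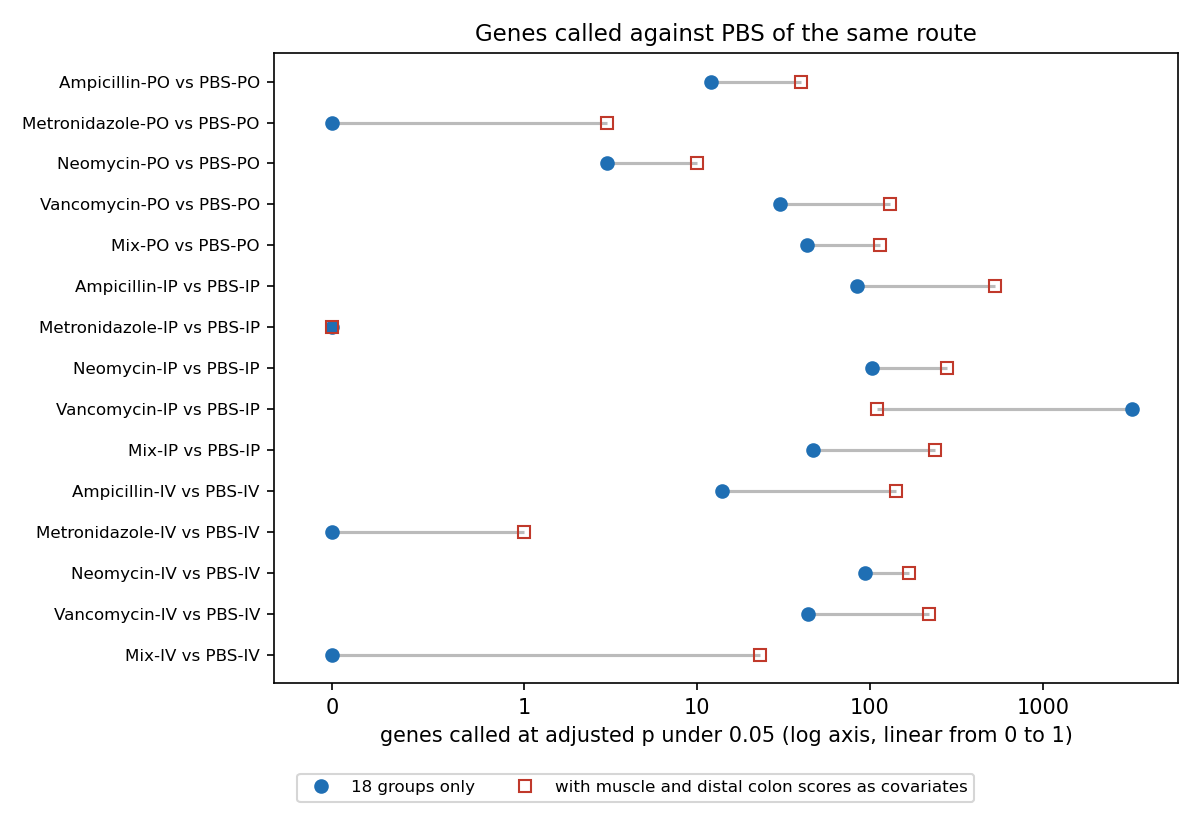
Genes called by limma at an adjusted p under 0.05 in each of the 15 comparisons with PBS of the same route (log axis, linear from 0 to 1). Filled circles are the counts from the 18 groups alone and open squares the counts with the muscle and distal scores as covariates. Vancomycin-IP moved from 3252 to 109 genes.

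**Figure D2:**
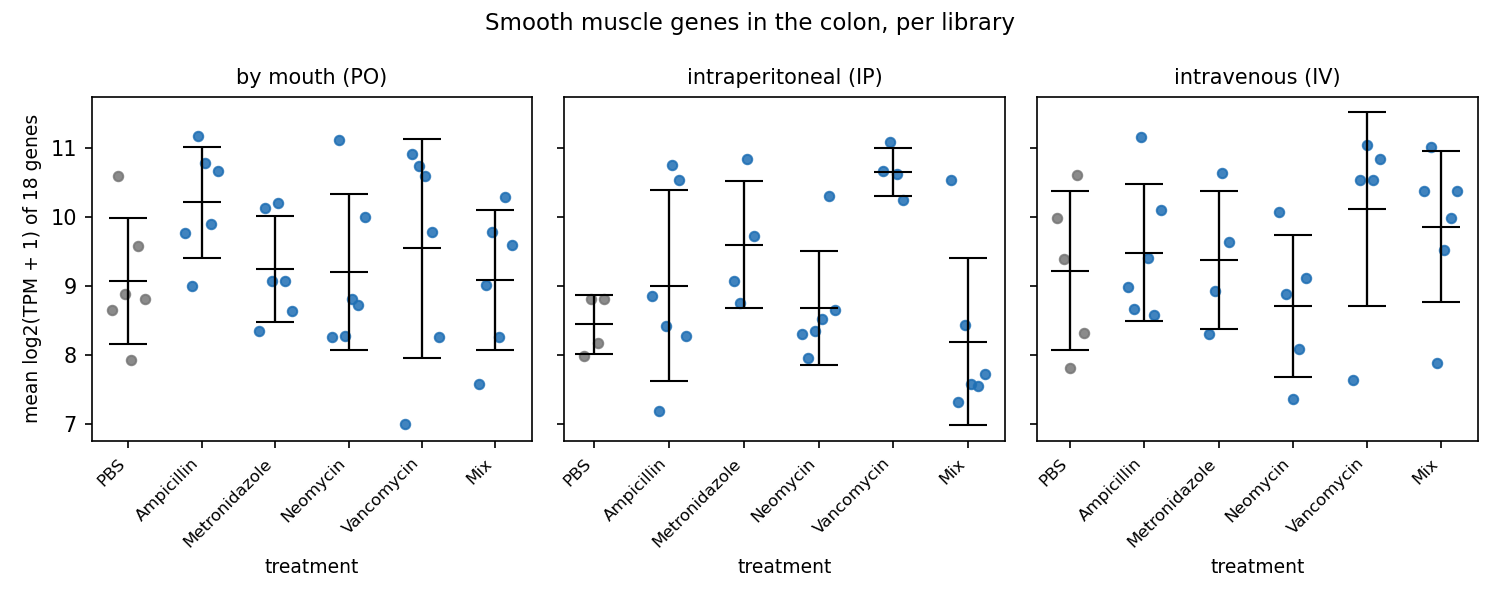
Smooth muscle score of every library (mean log2(TPM + 1) of 18 genes) by group, 1 point per library, with the group mean ± SD. The Vancomycin-IP libraries had a mean of 10.7 and the PBS-IP libraries of 8.44.

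Neomycin given into the peritoneum raised interferon-stimulated genes. Ifi44, an interferon-induced gene, stood at 48.7 ± 17.4 TPM (n = 6) against 2.99 ± 2.19 in PBS-IP (n = 4), a log2 fold change of 3.695 (SE 0.45, limma adjusted p = 1.07e-08). Oas2, a sensor of double-stranded RNA, rose by 3.975 to 170.1 ± 64.4 TPM. Isg15, the ubiquitin-like modifier, rose by 2.86 to 199.8 ± 90.2 TPM from 27.9 ± 20.7, and Ifi27l2a rose by 3.30. Of the 25 genes tested on the type I interferon list, 18 rose, none fell and 7 were not called over all genes, and 24 rose when adjusted over the list alone. The list's median log2 fold change was 2.18, and its camera test held with an estimated correlation (adjusted p = 4.63e-06). On the interferon gamma list 9 of 25 rose, among them the immunity-related GTPases Irgm2 (1.496) and Igtp (1.67), and 18 rose when adjusted over the list alone (adjusted p = 0.000922 with an estimated correlation). The 13 genes of the mitochondrial genome fell as a list, with a median of -0.998, no member called over all genes and 10 lower when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). In all, 98 genes rose and 5 fell. The 5 were Coq10b, a coenzyme Q binding protein (-0.72), Htra4 (-0.76) and the predicted genes Gm7331, Gm16378 and Gm10051, of which all but Coq10b were named after their values were seen. Coq10b was not called without PBS-IP replicates 1 or 4 (adjusted p up to 0.294). With PBS-IP replicates 1, 2 and 4 left out in turn the count was 67, 53 and 51. The count was 280 with the covariates, 58 without the 12 libraries whose columns were appended to the table, and 69 (58 higher, 11 lower) with quantile normalization. A fit of these 2 groups alone called 13 genes, without Oas2, Isg15 and Coq10b.

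Neomycin given into a vein gave a rise in interferon genes of like size. Ifi44 rose by 3.715 (SE 0.44, limma adjusted p = 8.02e-09), from 2.77 ± 1.65 TPM (n = 5) to 47.3 ± 17.5 (n = 5). Isg15 rose by 3.62 to 194 ± 68.6 TPM from 18.6 ± 13.8, and Rsad2, the antiviral protein viperin, rose by 2.96. On the type I interferon list 20 of 25 genes rose and 24 when adjusted over the list alone, with a median of 2.41 (adjusted p = 4.63e-06 with an estimated correlation). On the interferon gamma list 9 rose and 13 when adjusted over the list alone, including Irgm1 (1.60), Irgm2 (1.61) and Gbp7 (1.45), with an adjusted p = 0.00116 with an estimated correlation. The mitochondrial genome list fell with a median of -1.004, and all 13 members were lower when adjusted over the list alone (adjusted p = 0.713 with an estimated correlation). B cell genes fell as a list, with a median of -1.14 and no member called (adjusted p = 0.85 with an estimated correlation). In all 93 genes rose and 0 fell, with 1236 genes at an unadjusted p under 0.05 in either direction and 1 lower gene with quantile normalization (87 higher). With PBS-IV replicate 4 left out the count was 51. With the covariates 168 genes were called, and in a fit of these 2 groups alone 17, without Rsad2, Irgm1 and Gbp7.

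By mouth neomycin changed few genes. Heme oxygenase 1 (Hmox1), which degrades heme and is induced by oxidative stress, rose by 2.64 (SE 0.47, limma adjusted p = 0.00454). Its level was 85.9 ± 126 TPM (n = 6), from 3.01 to 303 between libraries, against 2.90 ± 0.425 in PBS-PO (n = 6), and 4 of the 6 libraries lay above the highest PBS library. Hmox1 was not called without Neomycin-PO replicates 3 or 5 (adjusted p up to 0.066). The other called genes were Tgs1, a cap methyltransferase (1.66), and the predicted gene Gm19220 (1.06), the latter named after its value was seen. Tgs1 was not called without Neomycin-PO replicates 2 or 6 or PBS-PO replicates 1, 2, 3 or 5 (adjusted p up to 0.366). The B cell list rose with a median of 1.92 and the list of MHC class II presentation with a median of 1.22 (camera). No member of either was called, and the adjusted p values with an estimated correlation were 0.744 and 0.720. The type I interferon list was not called, with Ifi44 at 0.56 (SE 0.40) and Isg15 at -0.05 (SE 0.52). With Neomycin-PO replicates 1, 2, 4 and 6 left out in turn the count was 5, 1, 8 and 1, and with PBS-PO replicates 5 and 6 left out in turn the count was 1 and 6. The count was 10 with the covariates and 0 in a fit of these 2 groups alone (limma).

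The F test of equal neomycin effects across the 3 routes called 15 genes. The 6 with the smallest adjusted p were the E3 ubiquitin ligase Dtx3l, Ifi27l2a, Ifit3b, Irgm2, Ifi44 and Ifit3, all interferon-stimulated. Dtx3l had log2 fold changes of 0.03 by mouth, 1.35 IP and 1.54 IV (limma adjusted p = 0.000219). For Ifi44 these were 0.56, 3.695 and 3.715 (limma adjusted p = 0.000586), and for Irgm2 0.09, 1.496 and 1.61. Ifit3 and Ifit3b, Oas1a and Oas1g, and Apol9a and Apol9b are near-identical copies whose values TPM estimation can share out, so single members are uncertain. Route differences of whole lists were tested only for the interferon and clock lists, picked after the data were seen. The type I interferon list differed between IP and PO (adjusted p = 3.57e-06 with an estimated correlation) and between IV and PO (adjusted p = 0.000164). The interferon gamma list did too, with camera adjusted p = 0.00282 and 0.0147. Among genes called against PBS, 65 rose both IP and IV, where independent lists of that length would share 0.534. Those comparisons have no library in common. They do share each gene's variance estimate from the single fit, so their lists are not fully independent. The F test called 41 genes with the covariates and 9 with quantile normalization. It called 0 genes for ampicillin, metronidazole, vancomycin, the mix and PBS itself, with 241, 156, 1127, 406 and 386 genes at an unadjusted p under 0.05. With array weights it called 2977 for vancomycin, 1988 for the mix and 779 for PBS.

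**Figure D3:**
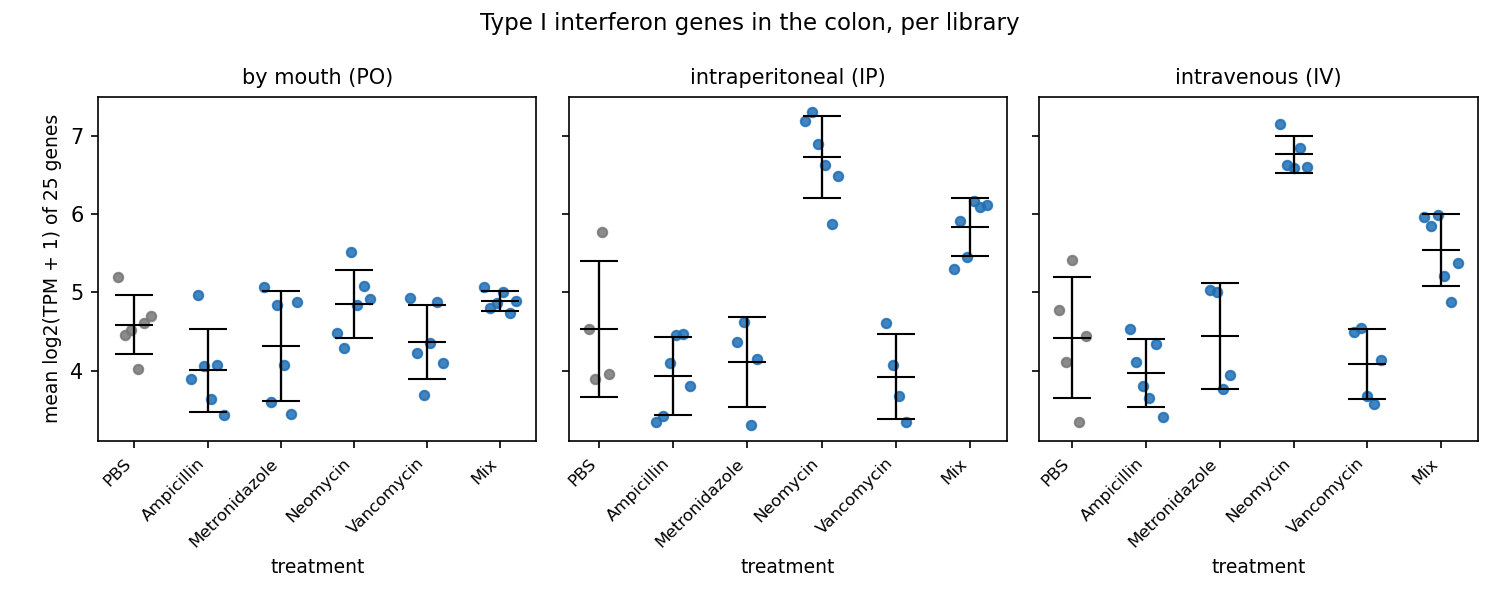
Mean log2(TPM + 1) of the 25 type I interferon genes in every library, by group, 1 point per library, with the group mean ± SD. All 6 Neomycin-IP and all 5 Neomycin-IV libraries lay above the highest PBS library of their route. The group means were 6.73 and 6.77, against 4.54 and 4.42 for PBS.

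Genes of the output arm of the circadian clock stood lower after ampicillin by mouth than in PBS-PO. For this and the clock differences that follow, the hour of collection and a chance phase of the PBS libraries stayed open, as told below. Dbp, a clock-controlled transcription factor, fell by 2.50 on the log2 scale (SE 0.44, limma adjusted p = 0.000949), from 229 ± 79.9 TPM (n = 6) in PBS-PO to 45.3 ± 26.3 (n = 6). Ciart, a repressor within the clock, fell by 2.27, Per3 fell by 1.65 and the deubiquitinase Usp2 fell by 1.77, while Nfil3, which binds the same DNA sites as Dbp, rose by 1.89. The clock list had 1 member higher, 4 lower and 13 not called, and 4 higher and 6 lower when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation). Cholesterol synthesis fell as a list, with a median of -0.48, the mevalonate pathway enzyme Mvd called (-1.33) and 10 of 24 lower when adjusted over the list alone (adjusted p = 0.744 with an estimated correlation). Mvd was not called without Ampicillin-PO replicates 3, 4, 5 or 6 or PBS-PO replicates 3, 4, 5 or 6 (adjusted p up to 0.213). Usp2 was not called without PBS-PO replicate 3 (adjusted p up to 0.0563). The smooth muscle list rose (median 1.19, 0 of 18 called) and the goblet cell list fell (median -1.25, 0 of 16 called), with adjusted p = 0.85 and 0.824 with an estimated correlation, and the muscle score was higher by 1.14 (exact p = 0.0433, adjusted p = 0.643). In all 4 genes rose and 8 fell. The other higher genes were Leo1, a subunit of the Paf1 transcription elongation complex (0.77), Mb21d2 (0.62) and Rasl11a (1.77), the last named after its value was seen. Mb21d2 was not called without Ampicillin-PO replicates 3, 4 or 6 or PBS-PO replicates 1, 3, 4 or 5 (adjusted p up to 0.281). With Ampicillin-PO replicate 6 left out the count was 7, and with PBS-PO replicates 2 and 4 left out in turn the count was 26 and 7. With the covariates 40 genes were called, all 12 among them, and in a fit of these 2 groups alone 0 genes (limma).

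Clock output genes also stood lower after ampicillin IP. Dbp fell by 2.82 (SE 0.50, limma adjusted p = 0.00193), from 225 ± 51.9 TPM (n = 4) to 34.5 ± 19.6 (n = 6), and Ciart fell by 2.14. Nr1d2, a nuclear receptor of the clock, fell by 1.22, and Npas2, a partner of Arntl, rose by 1.92 from 8.30 ± 1.67 to 33.9 ± 3.82 TPM. The sodium-phosphate cotransporter Slc34a2 rose by 2.86 (SE 0.62), from 11.6 ± 3.85 to 90.6 ± 27.6 TPM, and the pseudokinase Trib1 rose by 1.74. Usp2, lower by mouth, was not called (-0.79, limma adjusted p = 0.485). The clock list had 2 members higher, 4 lower and 12 not called, and was not called by camera (adjusted p = 0.0533). Cholesterol synthesis fell (median -0.58), with 0 members called and 12 of 24 lower when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation). The list of proliferation genes fell with a median of -1.04, 0 called and 5 lower when adjusted over the list alone (adjusted p = 0.841 with an estimated correlation). Of 84 called genes 70 rose and 14 fell. With Ampicillin-IP replicate 4 left out the count was 47, and with PBS-IP replicates 1, 2, 3 and 4 left out in turn the count was 38, 42, 136 and 34. The count was 525 with the covariates, 46 (30 higher, 16 lower) with quantile normalization and 23 without the appended libraries, where Slc34a2, Npas2 and Trib1 were not called. A fit of these 2 groups alone called 13 genes, without Nr1d2.

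After ampicillin IV Dbp stood lower by 2.74 (SE 0.47, limma adjusted p = 0.000693), at 47.5 ± 40.8 TPM (n = 6) against 248 ± 45.5 (n = 5), and Ciart by 2.21. Leo1 rose by 0.94 (limma adjusted p = 0.000147). Coq10b fell by 0.90, as it did by 0.83 PO and by 0.91 IP. The clock list had 2 members higher (Npas2 1.59, Arntl 1.92), 4 lower and 12 not called, and 5 higher and 9 lower when adjusted over the list alone (adjusted p = 0.478 with an estimated correlation). Npas2 was not called without Ampicillin-IV replicates 1, 2 or 4 or PBS-IV replicates 1, 2, 3 or 4 (adjusted p up to 0.203). Arntl was not called without Ampicillin-IV replicates 1, 2, 3, 4 or 6 or PBS-IV replicates 1, 2, 3 or 4 (adjusted p up to 0.208). Cholesterol synthesis fell again (median -0.46, 0 called, 3 lower when adjusted over the list alone, adjusted p = 0.713 with an estimated correlation). In all 9 genes rose and 5 fell, the 5 being Dbp, Ciart, Per3, Usp2 and Coq10b, and a fit of these 2 groups alone called 0 genes (limma). Per3 was not called without Ampicillin-IV replicates 1 or 3 or PBS-IV replicate 2 (adjusted p up to 0.124). Usp2 was not called without Ampicillin-IV replicates 1, 3, 4 or 6 or PBS-IV replicates 1, 2, 3 or 5 (adjusted p up to 0.269). Between routes, PO and IP shared 3 higher and 4 lower genes, PO and IV 1 and 5, and IP and IV 4 and 4, each against under 0.05 expected of independent lists. These lists too share each gene's variance estimate and so are not fully independent. With Ampicillin-IV replicates 1 and 2 left out in turn the count was 6 and 8, and with PBS-IV replicates 2 and 4 left out in turn the count was 5 and 9. The count was 141 with the covariates, 9 (4 higher, 5 lower) with quantile normalization and 5 without the appended libraries, where Ciart, Per3, Usp2 and Arntl were not called.

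Clock genes differed from PBS-PO after vancomycin by mouth as well. Ciart fell by 2.665 (SE 0.38, limma adjusted p = 1.22e-05), from 23.9 ± 10.6 TPM (n = 6) to 2.65 ± 0.575 (n = 6). Dbp fell by 2.43 and Per3 by 1.64, the latter to 22.3 ± 7.44 TPM, and Nfil3 rose by 1.615. The clock list had 1 member higher, 5 lower and 12 not called, and 4 higher and 7 lower when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). The chemokine Cxcl2, which draws neutrophils, rose by 0.54 at a level of 0.674 ± 0.627 TPM. Cxcl2 was not called without Vancomycin-PO replicates 1, 2 or 5 or PBS-PO replicates 1 or 6 (adjusted p up to 0.246). Only 5 genes rose, Cxcl2, Nfil3, the immediate early gene Ier5 (0.87), Pole4 (0.51) and the protease Adamts4 (0.82), the last named after its value was seen. Ier5 was not called without Vancomycin-PO replicates 1, 3, 4 or 5 or PBS-PO replicates 3 or 6 (adjusted p up to 0.13). Pole4 was not called without Vancomycin-PO replicates 2, 3, 4, 5 or 6 or PBS-PO replicates 1, 3, 4, 5 or 6 (adjusted p up to 0.336). The other 25 of the 30 called genes fell. With Vancomycin-PO replicates 2, 3, 4 and 5 left out in turn the count was 12, 11, 15 and 12, and with PBS-PO replicates 1, 2 and 6 left out in turn the count was 10, 15 and 13. The count was 131 with the covariates and 26 (8 higher, 18 lower) with quantile normalization. It was 2 without the 12 appended libraries, of which 3 are Vancomycin-PO and none PBS-PO, and there Dbp, Per3, Nfil3, Cxcl2, Ier5 and Pole4 were not called. A fit of these 2 groups alone called 3 genes, without Dbp, Nfil3, Cxcl2, Ier5 and Pole4.

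Vancomycin IP gave the longest list of changed genes in the comparisons with PBS fitted without covariates, 2726 higher and 526 lower, in the libraries with the higher muscle score. Once the covariates were fitted, Ampicillin-IP had the longest list, with 525 genes. Smooth muscle genes rose, 15 of 18 called and 17 when adjusted over the list alone, with a median of 2.17. Acta2, smooth muscle actin, stood at 7133 ± 1071 TPM (n = 4) against 1363 ± 488.9 (n = 4). The list's adjusted p was 0.85 with an estimated correlation. Its median was -0.02 with the covariates, which decides nothing, as the muscle covariate is the mean of these same 18 genes. Enteric neuron and glia genes (7 of 20 higher, among them Nos1 at 2.43) and fibroblast genes (7 of 16 higher, among them Col1a1 at 2.27) rose as lists, both with an adjusted p = 0.85 with an estimated correlation. Goblet cell genes fell, 4 of 16 called, such as Clca1 (-3.35) and Tff3 (-3.17), with an adjusted p = 0.841 with an estimated correlation. Thbs1, a matrix glycoprotein, rose by 3.61 (SE 0.76, limma adjusted p = 0.00328) and by 1.72 with the covariates. Il6st, the shared receptor chain of the interleukin-6 family, rose by 3.16 and stood at 1.34 (limma adjusted p = 0.225) with them. The clock genes Ciart (-2.70) and Nfil3 (2.73) kept -2.65 and 2.31. Acta2 was not called without Vancomycin-IP replicates 1 or 2 or PBS-IP replicate 1 (adjusted p up to 0.0669). Nos1 was not called without Vancomycin-IP replicates 1 or 2 or PBS-IP replicate 1 (adjusted p up to 0.0882). Col1a1 was not called without Vancomycin-IP replicates 1, 2 or 3 or PBS-IP replicate 1 (adjusted p up to 0.0654). Clca1 was not called without Vancomycin-IP replicates 1, 2 or 3 or PBS-IP replicates 1, 2 or 4 (adjusted p up to 0.17). Tff3 was not called without Vancomycin-IP replicates 1, 2 or 3 or PBS-IP replicates 1, 2 or 4 (adjusted p up to 0.176). With Vancomycin-IP replicates 1, 2 and 3 left out in turn the count was 608, 555 and 1424, and with PBS-IP replicates 1, 2 and 4 left out in turn the count was 925, 1925 and 1885. With the covariates 109 genes were called, 99 of them among the 3252, and with quantile normalization 2048 rose and 1574 fell. Without the appended libraries 5 genes were called, and of the genes named here only Nfil3 kept its call. Within the appended libraries (3 against 2) 5 genes were called and the muscle score differed by 2.16, and within the rest (1 against 2) 6 genes and 2.27.

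After vancomycin IV Ciart stood lower by 1.90 (SE 0.42, limma adjusted p = 0.035), at 6.73 ± 4.56 TPM (n = 5) against 24.1 ± 6.99 (n = 5). Dbp stood at -1.61 (limma adjusted p = 0.0982) and was not called. Ciart was not called without Vancomycin-IV replicate 4 or PBS-IV replicates 3 or 5 (adjusted p up to 0.189). Dek, a chromatin protein, rose by 0.92 and Ccng1, a p53 target, by 1.01. Dek was not called without Vancomycin-IV replicates 4 or 5 or PBS-IV replicates 3 or 5 (adjusted p up to 0.0835). Ccng1 was not called without Vancomycin-IV replicates 3, 4 or 5 or PBS-IV replicates 2, 3 or 5 (adjusted p up to 0.189). The clock list fell with 1 of 18 members called (median -0.32, adjusted p = 0.841 with an estimated correlation). The smooth muscle list rose (median 0.92, 0 called, adjusted p = 0.891 with an estimated correlation), and the muscle score was higher by 0.89 (exact p = 0.278). In all 39 genes rose and 5 fell, the others being the pancreatic protease Ctrl and, named after their values were seen, Ufsp1, Rpl30-ps9 and Gm46223. Ctrl was not called without Vancomycin-IV replicates 2, 3, 4 or 5 or PBS-IV replicates 2, 3 or 5 (adjusted p up to 0.27). With Vancomycin-IV replicates 1, 2, 3, 4 and 5 left out in turn the count was 381, 10, 8, 0 and 4, and with PBS-IV replicates 2, 3, 4 and 5 left out in turn the count was 6, 1, 437 and 4. The count was 218 with the covariates, 5 without the appended libraries, where Ciart, Dek, Ccng1 and Ctrl were not called, 5 (2 higher, 3 lower) with quantile normalization, 0 in a fit of these 2 groups alone (limma), 1 within the appended libraries (2 against 2) and 6 within the rest (3 against 3).

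**Figure D4:**
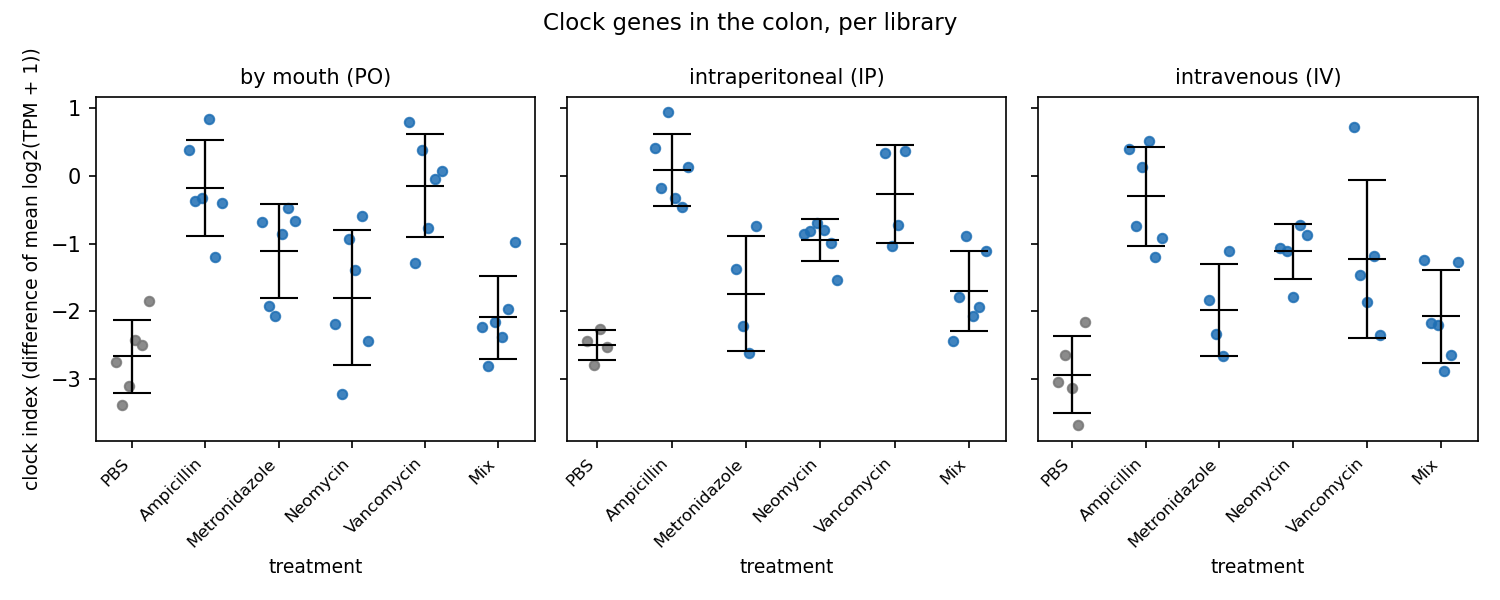
Clock index of every library, the mean log2(TPM + 1) of Arntl, Clock, Npas2 and Nfil3 minus that of 9 output and repressor genes (Dbp, Tef, Hlf, Per2, Per3, Ciart, Nr1d1, Nr1d2, Usp2), by group with mean ± SD. The index was defined after the data were seen. PBS means were -2.67, -2.51 and -2.94 for PO, IP and IV, and ampicillin means -0.18, 0.09 and -0.30.

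Metronidazole changed no single gene in any route by limma, with 555 (PO), 1221 (IP) and 252 (IV) genes at an unadjusted p under 0.05 and 3, 0 and 1 called with the covariates. Array weights called 3, 19 and 48. Ciart and Dbp, named here after their values were seen, stood at -1.91 (SE 0.38, limma adjusted p = 0.0517) and -1.17 (SE 0.44) after the oral dose (n = 6 and 6). The clock list fell with a median of -0.47 PO, with 1 member higher and 6 lower when adjusted over the list alone, and with a median of -0.34 IV, with adjusted p = 0.313 and 0.478 with an estimated correlation. Immediate early and heat shock genes rose PO (median 0.49, 0 of 18 called, 4 higher when adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). Cholesterol synthesis fell in all 3 routes, with medians of -0.27, -0.52 and -0.35 and 0 of 24 called in each (adjusted p = 0.841, 0.841 and 0.713 with an estimated correlation). In Metronidazole-IP the smooth muscle list rose (median 1.15, 0 called, adjusted p = 0.85 with an estimated correlation), and the muscle score was higher by 1.15 (exact p = 0.0857, n = 4 and 4). With Metronidazole-PO replicate 3 left out the count was 1, and with PBS-PO replicates 5 and 6 left out in turn the count was 1 and 3. With Metronidazole-IV replicate 3 left out the count was 2. In simulated data on 17083 genes, the same test recovered 54%, 38% and 52% of genes changed 2-fold in Metronidazole-PO, -IP and -IV. Those genes varied independently and lay above a set mean level, so these shares need not hold for the real libraries.

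The mix by mouth raised Fkbp5 and lowered Aqp8 and Duoxa2. Fkbp5, a cochaperone induced by glucocorticoids, rose by 2.20 (SE 0.50, limma adjusted p = 0.0237), from 85.1 ± 28.8 TPM (n = 6) to 409 ± 157 (n = 6), and the growth factor Bmp3 by 1.84. The glucocorticoid list rose with a median of 0.63, 1 of 15 called and 2 when adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). Aqp8, a water channel of surface colonocytes, stood at 66.2 ± 121 TPM against 649.7 ± 309 (log2 fold change -5.34, SE 1.21, limma adjusted p = 0.0237), and at -3.62 with the covariates. Duoxa2, the maturation factor of an epithelial oxidase, fell by 2.96, and antimicrobial and mucosal defence genes fell as a list with 1 of 23 called (median -0.40, adjusted p = 0.563 with an estimated correlation). Macrophage and dendritic cell genes fell, with a median of -0.48, 0 of 20 called and 5 when adjusted over the list alone (adjusted p = 0.563 with an estimated correlation). The distal score differed from PBS-PO by -1.76 (exact p = 0.0844). Fkbp5 was not called without Mix-PO replicates 1, 2, 3 or 4 or PBS-PO replicates 3 or 6 (adjusted p up to 0.123). Bmp3 was not called without Mix-PO replicate 4 (adjusted p up to 0.0702). Aqp8 was not called without Mix-PO replicates 1, 2, 3 or 4 or PBS-PO replicates 3 or 6 (adjusted p up to 0.11). Duoxa2 was not called without Mix-PO replicates 2, 3 or 4 or PBS-PO replicates 5 or 6 (adjusted p up to 0.106). In all 36 genes rose and 7 fell. With Mix-PO replicates 1, 2, 3, 4 and 5 left out in turn the count was 3, 2, 1, 0 and 160, and with PBS-PO replicates 3 and 6 left out in turn the count was 16 and 5. With quantile normalization only Bmp3 was called (1 higher, 0 lower), and with the covariates 114. A fit of these 2 groups alone called 7 genes, without Bmp3 and Aqp8.

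Interferon genes also stood higher after the mix IP, though the random regroupings described below could not exclude chance for its gene count. Ifi44 rose by 2.25 (SE 0.45, limma adjusted p = 0.0077), from 2.99 ± 2.19 TPM (n = 4) to 18.8 ± 11.5 (n = 6), and Oasl2 by 2.34. Ifi44 was not called without PBS-IP replicates 1, 2 or 4 (adjusted p up to 0.0963). Oasl2 was not called without Mix-IP replicate 4 or PBS-IP replicates 1, 2 or 4 (adjusted p up to 0.147). Hbegf, a ligand of the epidermal growth factor receptor, rose by 2.15. Hbegf was not called without PBS-IP replicates 1 or 2 (adjusted p up to 0.0963). On the type I interferon list 6 of 25 rose and 18 when adjusted over the list alone, with a median of 1.17 (adjusted p = 0.176 with an estimated correlation). That list differed between IP and PO (adjusted p = 0.00441 with an estimated correlation), in a test chosen after the data were seen. Crypt stem and transit cell genes fell, with a median of -0.94, 0 of 14 called and 8 lower when adjusted over the list alone (adjusted p = 0.681 with an estimated correlation). Plasma cell genes fell with a median of -1.24 (0 of 15 called, adjusted p = 0.841 with an estimated correlation). In all 31 genes rose and 16 fell. With Mix-IP replicates 2, 4, 5 and 6 left out in turn the count was 8, 7, 14 and 315, and with PBS-IP replicates 1, 2, 3 and 4 left out in turn the count was 3, 4, 571 and 6. The count was 237 with the covariates, 30 with quantile normalization and 0 in a fit of these 2 groups alone (limma).

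The mix IV called 0 genes by limma, with 956 at an unadjusted p under 0.05. Other settings called 23 genes with the covariates, 4 with quantile normalization, 6 with a pseudocount of 10 and 249 with array weights. Ifi44, named after its value was seen, stood at 1.92 (SE 0.42, limma adjusted p = 0.0743). The type I interferon list rose with a median of 1.24, 0 of 25 called and 15 when adjusted over the list alone (adjusted p = 0.106 with an estimated correlation, and 0.0197 with the covariates as well). The interferon gamma list rose with a median of 0.61 and 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation). With Mix-IV replicates 1, 3 and 5 left out in turn the count was 1, 2 and 5, and with PBS-IV replicate 5 left out the count was 1.

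Against the mean of the 4 single antibiotics of its route, the mix differed in 281 genes by mouth (250 higher, 31 lower), 571 IP (81 higher, 490 lower) and 1 IV. The muscle score of the mix differed from that of the single antibiotics by -0.47 PO, -1.17 IP and 0.44 IV. The mean distal score was 2.081 in Mix-PO, against 3.275 to 4.472 in the groups of single antibiotics by mouth. It was 2.542 in Mix-IP, against 3.539 to 4.416, and 3.251 in Mix-IV, against 2.187 to 3.506. By mouth the mix was higher in Wee1, a cell cycle kinase under clock control (1.08, SE 0.19, limma adjusted p = 0.00177), and in Ciart (1.66), Cry2 (0.86), Fkbp5 (2.09), Pdxk (0.82) and Slc17a5 (1.01). Mean TPM of Ciart was 20.9 in Mix-PO, 6.55 over the single antibiotics and 23.87 in PBS-PO. IP the mix was higher in Xaf1, an interferon-induced gene (1.20, SE 0.19, limma adjusted p = 9.16e-05), Ciart (1.81), Oasl2 (1.97) and Apol9b (2.14), and lower in Pofut1 (-0.55) and Thbd, which encodes thrombomodulin (-0.93). The mean of the single antibiotics joins groups that differ. Neomycin-IP alone stood above Mix-IP in Oasl2 (409.1 against 278.5 TPM) and Apol9b (98.58 against 46.22 TPM). Mean TPM of Ciart was 21.04 in Mix-IP and 21.77 in PBS-IP. IV the gene was the chemokine Ccl2 (1.22, limma adjusted p = 0.041), named after its value was seen, with 412 genes at an unadjusted p under 0.05. The covariates left 68 genes by mouth, 53 of them shared, 47 IP, 23 of them shared, and 4 IV. With quantile normalization 132 genes were called by mouth and 122 IP, the latter 90 higher and 32 lower.

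Over the 36 lists and 15 comparisons camera called 177 of 540 tests with its preset correlation of 0.01 and 4 with an estimated one, the 4 being both interferon lists after neomycin IP and IV. The smallest adjusted p of the rest with an estimated correlation was 0.106. The circadian clock list was called lower in 8 comparisons, cholesterol synthesis lower in 11 and higher in 1 (Neomycin-IV), and the mitochondrial genome lower in 9. Goblet cells were lower in 9, xenobiotic and Nrf2 metabolism lower in 9, plasma cells lower in 8, proliferation lower in 7 and higher in 1, and crypt stem and transit cells lower in 6. Smooth muscle was higher in 6 and lower in 1, enteric neurons and glia and fibroblasts and matrix each higher in 4 and lower in 1, and adipose tissue higher in 1. The type I interferon list was higher in 4 and lower in 7, interferon gamma higher in 5 and lower in 5, antimicrobial and mucosal defence lower in 4, and inflammatory cytokines and NF-kB targets higher in 2 and lower in 2. B cells were higher in 3 and lower in 4, MHC class II presentation higher in 2 and lower in 4, T and natural killer cells higher in 1 and lower in 3, macrophages and dendritic cells higher in 1 and lower in 3, and type 17 immunity lower in 1. Absorptive colonocytes were higher in 1 and lower in 5, enteroendocrine cells lower in 5, tuft cells higher in 1, endothelium and blood lower in 3, and ion and water transport higher in 1 and lower in 4. Nuclear oxidative phosphorylation was higher in 1 and lower in 5, PPAR, ketogenesis and fatty acid oxidation higher in 3 and lower in 2, glucocorticoid response higher in 1, immediate early and heat shock higher in 5, and unfolded protein and amino acid stress higher in 2. Mast cells and eosinophils, squamous epithelium, aryl hydrocarbon receptor targets, butyrate transport and sensing and bile acid handling were called in 0 comparisons. Neutrophils and pancreas had 4 tested members each and were not tested. With the covariates 127 tests were called, 94 of them among the 177, and smooth muscle was called in 0. The last was fixed in advance, since the muscle covariate is the mean of the smooth muscle genes.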

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

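Of the tests of explanations below, those of the muscle share and of T cells and macrophages were written before their results were seen, and all others, with the random regroupings, were chosen after. Each group of values was searched for a library far from the rest, and 9 of 115 groups had such a library, where about 1 in 20 would by chance. The clock index of Neomycin-IP replicate 6 was -1.537 (next -0.9879). Muscle scores were 10.54 in Mix-IP replicate 1 (next 8.43), 10.3 in Neomycin-IP replicate 5 (next 8.653) and 7.635 in Vancomycin-IV replicate 1 (next 10.53). In PBS-IP, Slc34a2 was 17.31 TPM in replicate 4 (next 10.11), Ifi27l2a 6.737 in replicate 1 (next 10.19) and Thbs1 67.53 in replicate 3 (next 35.83). Npas2 was 27.1 in Ampicillin-IP replicate 5 (next 33.5) and Irgm2 52.3 in Neomycin-IV replicate 3 (next 84.4). Between routes, 15 genes differed for neomycin. List differences between routes were tests chosen after the data were seen. The type I interferon list differed for neomycin IP minus PO (adjusted p = 3.573e-06, camera) and IV minus PO (0.0001635) and for the mix IP minus PO (0.004412), and the interferon gamma list for neomycin (0.002815 and 0.01471).

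Smooth muscle genes stood higher after intraperitoneal vancomycin. Slopes on the muscle score, fitted in the 89 libraries of the other groups, predicted the fold changes of 3237 called genes outside the muscle list with r = 0.9414, which fits a larger share of muscle in the tissue pieces. The muscle score differed by at least 2.161 within the appended libraries and within the rest, which argues against a difference between these sets as the source. The sets held 3 Vancomycin-IP against 2 PBS-IP libraries and 1 against 2, too few to exclude it. Whether the appended libraries were made at another time is not given in the sources used here. Whether vancomycin itself alters the wall could not be told: the exact p of the score, 0.02857, is the smallest that 4 against 4 libraries allow, so its adjusted value of 0.6428 over 30 tests decides nothing.

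Clock output genes stood lower after ampicillin and vancomycin. The mean clock index was above PBS in every antibiotic group of every route, by 0.5807 (Mix-PO) to 2.64 (Ampicillin-IV). Apart from ampicillin and vancomycin, the adjusted exact p was under 0.05 for neomycin IP (1.558, adjusted exact p = 0.01429) and IV (1.827, adjusted exact p = 0.01701). It was also under 0.05 for metronidazole PO (1.559, adjusted exact p = 0.01624). The difference after vancomycin IV was 1.714. A chance phase of the PBS libraries stayed open. Against the metronidazole, neomycin and mix libraries of the route the clock index had a permutation p of at most 0.00099 for ampicillin, 0.00103 for vancomycin PO, 0.00843 for vancomycin IP and 0.2642 for vancomycin IV, but the genes of the index were chosen after these libraries were seen. The order of the 5 antibiotic treatments varied between routes (lowest Spearman rho 0.5), and the clock hours of collection are not given in the sources used here. The mix, which holds both drugs, differed from ampicillin by -1.908 PO, -1.795 IP and -1.773 IV and from vancomycin by -1.946, -1.445 and -0.8466 (exact p = 0.1688 for the last and at most 0.01429 for the others), and without the amount of each drug in the mix an action of the drugs stayed open too.

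Interferon genes stood higher after injected neomycin. A rise of T cell or macrophage genes as wide as that of the interferon genes was excluded, as the largest median of their lists was 0.2793. Such a median cannot exclude a rise in a small subset of immune cells, and neutrophils were not tested. A few libraries carrying the response was excluded, as 0 injected neomycin libraries lay at or below the highest PBS library. The injected mix had a higher mean interferon score than PBS in both routes. The larger exact p of the mix was 0.01732, and 0.06495 when adjusted over the 15 comparisons. Injected neomycin alone had an adjusted exact p = 0.05953 in both routes. Its exact p values, 0.004762 IP and 0.007937 IV, were the smallest that these group sizes allow. The exact p values of the mix, 0.01429 IP and 0.01732 IV, were above the smallest possible, 0.004762 and 0.002165. Group size alone therefore does not account for its adjusted value. Of 6 mix libraries in each route, 4 IP and 3 IV lay above the highest PBS library. Whether neomycin or a substance in its solution was the source stayed open.

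The same libraries were regrouped at random, 100 times or 35 where no more were possible, the real grouping included, and a share under 0.05 was taken to exclude chance, with no adjustment over the results tested. For the grouping alone, chance could be excluded for Ampicillin-PO (12 genes, highest other 1, as many in 1 of 100), Ampicillin-IP (84, highest other 6, 1), Ampicillin-IV (14, highest other 6, 1), Neomycin-IP (103, highest other 47, 1), Neomycin-IV (93, highest other 49, 1) and Vancomycin-IP (3252, highest other 8, 1 of 35, the smallest share possible). A chance draw of pieces with more muscle in Vancomycin-IP stayed open, as above. So did a chance phase of the PBS libraries for the clock genes of the ampicillin and vancomycin groups. Regrouping cannot tell a treatment from anything else that a whole group shared, such as the hour of collection. By that bound alone, with other groupings that called more genes, chance could also be excluded for Vancomycin-PO (30, highest other 4034, 3), Mix-PO (43, highest other 103, 2), Vancomycin-IV (44, highest other 5077, 3), the mix against single antibiotics PO (281, highest other 2966, 3) and IP (571, highest other 4240, 3), and neomycin by route (15, highest other 37, 4). Chance could not be excluded for Neomycin-PO (3, highest other 549, 6), Mix-IP (47, highest other 3538, 6) and the mix against single antibiotics IV (1, highest other 3854, 11). Where 0 genes were called (limma) every regrouping calls as many, so the count says nothing about chance. This held in 100 of 100 for Metronidazole-PO (highest other 7), Metronidazole-IV (9) and Mix-IV (1174), in 35 of 35 for Metronidazole-IP (1), and in 100 of 100 for the routes of ampicillin (2), metronidazole (2), vancomycin (4139), the mix (237) and PBS (4). Regroupings that call many times the real count point to a structure of the samples. In the highest regrouping the muscle score differed by -2.117 for Vancomycin-PO, 1.861 for Vancomycin-IV and -1.49 for Mix-IV, but by -0.413 for Neomycin-PO and -0.06681 for Mix-IP. For the mix against single antibiotics it differed by 1.152 PO, -1.726 IP and 1.339 IV.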

How the results depend on the processing

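The settings below moved a count by over 1.5 times or changed whether anything was called, and the cause was not tested. The covariates, alone or with other changes, the term for the appended libraries and the removal of those libraries were alternatives chosen after the data were seen, and the rest were chosen before. A pseudocount of 10 gave 1 for Metronidazole-PO, 67 for Mix-PO, 70 for Vancomycin-IV, 6 for Mix-IV, 129 for the mix against single antibiotics IP and 30 for the routes of neomycin. Testing all genes gave 2 for Metronidazole-PO and 10 for Neomycin-PO. Quantile normalization gave 1 for Metronidazole-PO, 1 for Mix-PO, 46 for Ampicillin-IP, 30 for Mix-IP, 9 for Ampicillin-IV, 5 for Vancomycin-IV, 4 for Mix-IV, 132 for the mix against single antibiotics PO, 122 for the mix against single antibiotics IP and 9 for the routes of neomycin. Array weights gave 3095 for Ampicillin-PO, 3 for Metronidazole-PO, 7 for Neomycin-PO, 88 for Vancomycin-PO, 1626 for Mix-PO, 1655 for Ampicillin-IP, 19 for Metronidazole-IP, 1140 for Neomycin-IP, 9897 for Vancomycin-IP, 6264 for Mix-IP, 24 for Ampicillin-IV, 48 for Metronidazole-IV, 5310 for Vancomycin-IV, 249 for Mix-IV, 3421 for the mix against single antibiotics PO, 7310 for the mix against single antibiotics IP, 92 for the mix against single antibiotics IV, 34 for the routes of neomycin, 2977 for the routes of vancomycin, 1988 for the routes of the mix and 779 for the routes of PBS.

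With the replicate number as a block (replicate block) the counts were 1 for Metronidazole-PO, 46 for Ampicillin-IP, 25 for Mix-IP, 27 for Vancomycin-IV and 0 for the mix against single antibiotics IV. With a library-number block they were 3 for Vancomycin-IV and 5 for Mix-IV. Whether the numbers pair the samples was not tested, and correlations per pair by replicate number ran from -0.70 to 0.84. Their mean was 0.361 for Neomycin-PO, where 3 of 6 libraries correlated best with the PBS library of their own number. For Ampicillin-IV it was -0.3091, with 0 of 5. By library number 3 of 4 did so for Ampicillin-IP and 0 of 4 for Neomycin-IP. The route test of PBS could not be fitted with a replicate block.

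A fit of only the compared groups gave 0 for Ampicillin-PO, 0 for Neomycin-PO, 3 for Vancomycin-PO, 7 for Mix-PO, 13 for Ampicillin-IP, 13 for Neomycin-IP, 5266 for Vancomycin-IP, 0 for Mix-IP, 0 for Ampicillin-IV, 17 for Neomycin-IV, 0 for Vancomycin-IV, 18 for the mix against single antibiotics PO, 59 for the mix against single antibiotics IP, 0 for the mix against single antibiotics IV and 2 for the routes of neomycin. Muscle and distal scores as covariates gave 40 for Ampicillin-PO, 3 for Metronidazole-PO, 10 for Neomycin-PO, 131 for Vancomycin-PO, 114 for Mix-PO, 525 for Ampicillin-IP, 280 for Neomycin-IP, 109 for Vancomycin-IP, 237 for Mix-IP, 141 for Ampicillin-IV, 1 for Metronidazole-IV, 168 for Neomycin-IV, 218 for Vancomycin-IV, 23 for Mix-IV, 68 for the mix against single antibiotics PO, 47 for the mix against single antibiotics IP, 4 for the mix against single antibiotics IV, 41 for the routes of neomycin and 111 for genes shared between routes (65). A term for the appended libraries gave 5136 for Vancomycin-IP, 121 for Mix-IP, 97 for Vancomycin-IV, 752 for the mix against single antibiotics PO, 2761 for the mix against single antibiotics IP, 0 for the mix against single antibiotics IV and 23 for the routes of neomycin. Without the appended libraries there were 2 for Vancomycin-PO, 23 for Ampicillin-IP, 58 for Neomycin-IP, 5 for Vancomycin-IP, 71 for Mix-IP, 5 for Ampicillin-IV, 5 for Vancomycin-IV, 826 for the mix against single antibiotics PO, 174 for the mix against single antibiotics IP, 0 for the mix against single antibiotics IV and 29 for the routes of neomycin. Covariates and that term together gave 37 for Ampicillin-PO, 3 for Metronidazole-PO, 10 for Neomycin-PO, 86 for Vancomycin-PO, 115 for Mix-PO, 422 for Ampicillin-IP, 239 for Neomycin-IP, 128 for Vancomycin-IP, 72 for Mix-IP, 88 for Ampicillin-IV, 179 for Neomycin-IV, 276 for Vancomycin-IV, 18 for Mix-IV, 52 for the mix against single antibiotics PO, 30 for the mix against single antibiotics IP, 3 for the mix against single antibiotics IV, 38 for the routes of neomycin and 116 for genes shared between routes (65). An estimated correlation gave 4 for the gene lists (177). With an estimated correlation and covariates there were 5 for the gene lists (177). Without the appended libraries Vancomycin-IP keeps 1 library, which is then taken to vary as the other groups do.

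In the setting of covariates and term for the appended libraries, 2 genes changed sign. Csrp1 in Vancomycin-IP vs PBS-IP stood at -0.006259 (limma adjusted p = 0.9926), and Cnn1 in Vancomycin-IP vs PBS-IP at -0.001395 (limma adjusted p = 0.9993). Both are smooth muscle genes of the muscle covariate, so the fit removes their shared difference by construction.

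With each library left out in turn the counts ran from 7 to 26 for Ampicillin-PO, 0 to 3 for Metronidazole-PO, 1 to 8 for Neomycin-PO, 10 to 36 for Vancomycin-PO, 0 to 160 for Mix-PO, 34 to 136 for Ampicillin-IP, 0 to 0 for Metronidazole-IP, 51 to 116 for Neomycin-IP, 555 to 4576 for Vancomycin-IP, 3 to 571 for Mix-IP, 5 to 16 for Ampicillin-IV, 0 to 2 for Metronidazole-IV, 51 to 111 for Neomycin-IV, 0 to 437 for Vancomycin-IV and 0 to 5 for Mix-IV. Over all settings, 4990 values of 261 named genes in their comparisons were the same 3759 times, weaker 1229 times and of the other sign 2 times.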

Other observations

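The second axis of the libraries followed position along the colon. It carried 17.97% of the variance and ran with the distal score (r = -0.953). Its distal end held Hoxb13, Hoxd13, Mptx1 and the proton pump subunit Atp12a, and its other end Reg3b, Reg3g, the bile acid transporters Slc51a and Slc10a2, Cyp2c65 and Osr2. The next axis, with 6.27%, followed B cell genes (r = 0.672) such as Pax5, Cr2 and Cd79a, as lymphoid tissue in the piece would give.

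Libraries in the 12 appended columns differed from the rest in 175 genes once group, muscle and distal scores were fitted. Lower in them were Hmga1b (-1.87, limma adjusted p = 2.32e-09), the nuclear pore protein Tpr (-0.93), Rps15a (-1.12), Uchl1 (-1.43) and Reln (-1.45). Correlations between libraries of one group ran from 0.79 to 0.989, and the 10 most abundant genes took 7.47% to 27.9% of the TPM.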
